A study of Mus musculus with 2 samples.

How the data were processed

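DNase-seq libraries from hippocampus of male B6CASTF1/J mice aged 10 days formed 1 group of 2 biological replicates, numbered as in the labels. The labels give each replicate its own tissue sample. Both carry the same donor label, so whether any animal contributed to both is not given in the sources used here, and the spread between them measures only these 2 samples.

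Per the labels the assembly is mm10. The deposited region lists are in narrowPeak format and were derived from filtered alignments of each library separately and from a second, unnamed source, per the notes deposited with each sample. The caller, its version and its threshold are not given in the sources used here. The region value is a signal height that the authors deposited per region. It is the authors' own value and was used to rank, filter and describe regions. All heights in the shorter lists lay within 0.05 steps of whole multiples of 1 step, 0.00629 in replicate 1 and 0.00546 in replicate 2. This fits a window count divided by a factor per library, but that normalisation is stated only for a signal track not analysed here. The deposited false discovery rates of the cut rate per base, read as p-values adjusted by the authors, are listed up to 0.05. Tested on the files, every region of the shorter list held a base at 0.001 or lower, and regions of the longer list reached 0.0499. The shorter list, with 54546 and 74278 regions, was the main one, and the longer list, with 94187 and 131213, an alternative. The deposited footprint lists give a p-value of 0.01 in every row, read as a limit of the authors and not as a measurement. Adjacent regions overlapped each other in 1.44% and 2.70% of regions and were kept as listed. Sequencing depth was not given in the sources used here.

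Region ends lay within the chromosome lengths of the reference GRCm38 on all chromosomes used (1 to 19, X and Y). Genes and starts were from GENCODE mouse M21, with 21911 protein-coding genes. A promoter region lay within 1000 bp of any annotated start, and all others were distal. A gene was called accessible, or open, where a region lay within 1000 bp of any of its starts. Its locus was the gene body plus 10 kb on each side. Regions were shared where they overlapped by at least 1 bp. The overlap by chance came from 100 circular shifts within chromosomes.

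For 27 gene lists of cell types, tissues and functions, the accessible share was compared with all other protein-coding genes by a two-sided Fisher's exact test in each library, adjusted by Benjamini-Hochberg over the lists. A list was called where both libraries passed 0.05 in the same direction. H19, Kcnq1ot1 and Meg3 are not annotated as protein-coding and were left out. For distal regions the median count per gene was placed among 10000 random lists matched on locus length in 20 bins. Genes are not replicates, and the pair of libraries gives the only replicate check. Motifs, 30 consensus sequences searched on both strands, were counted in shared distal regions and in 1 control window per region. Controls had the same length, GC content within 2 percentage points and lay 5 to 50 kb away outside all regions; 1020 regions had none and were left out. Ratios carry 95% exact binomial intervals, which cover counting error only, and a control count of 0 was set to a floor of 3 counts over all controls. Matches in footprints were compared with up to 10 column shuffles of each consensus. Matches of regions to copies elsewhere in the assembled chromosomes were searched with BLAST 2.17.0, with a copy defined by 90% identity over 90% of the length. Copies on unlocalised and unplaced sequences of the assembly were not counted.

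Lists, motifs, tests, the alternatives described as planned and the rule for named genes were fixed before the data were examined. The rule names the 10 genes with the highest promoter regions, the 10 with most and the 10 with densest shared distal regions, in each list up to 3 genes with most distal regions and up to 3 without a promoter region, list genes open in 1 library, and genes of the 10 densest windows. Not all are named, 1 gene of a list is not reported here, and genes outside the rule serve as examples of lists in which every member was open. Alternatives covered the stronger 50% of regions, the longer list, equal numbers of regions, reciprocal overlap of 50%, promoter distances of 500 and 2500 bp, other loci and matching, flanks without GC matching, window sizes and each replicate on its own.

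On simulated data over 21911 genes, the promoter test called 262 of 350 lists planted at high accessibility, 318 of 350 planted at low accessibility, and 12 of 650 unchanged lists. The locus test called 28 of 35 lists planted with 4 times the regions and 0 of 95 unchanged lists. Its simulated genes held more regions than the real ones, which had a mean of 0.922 and a median of 0 shared distal regions. These counts therefore do not describe its power on the real data. The motif test, over 20000 windows of random bases, called 5 of 5 motifs planted in 3% of windows and 0 of 25 others. Several motifs called in the real regions were rarer, such as RFX at 0.225%, and real sequence is not made of random bases. The power and error rate of the motif test on the real data therefore remain unknown. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.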

Results

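Chromatin accessibility was measured by DNase-seq, in which the enzyme DNase I cuts DNA where it is not covered by nucleosomes, in hippocampus of male mice aged 10 days, a tissue the labels call a layer of hippocampus. The animals were B6CASTF1/J, first-generation hybrids of the C57BL/6J and CAST/EiJ strains. There was 1 group of 2 libraries, numbered 1 and 2 by the labels as biological replicates, each from its own tissue sample described as holding 3 males. The labels name no second condition, so the comparisons were between the replicates, between classes of genome sequence and between groups of genes. For each library the authors deposited 2 lists of accessible regions, a list of footprints, which are short protected stretches inside accessible DNA, and false discovery rates of the cut rate per base. The number of reads per library was not given in the sources used here, so no error from sequencing depth could be attached to a single value. All positions are on mm10 (GRCm38) and 1-based.

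In the hippocampus, 54546 regions were accessible in replicate 1 and 74278 in replicate 2, a mean of 64412 ± 13953 (SD, n = 2). They covered 0.403% and 0.593% of the genome, and their median width was 200 bp in both libraries. Most of the smaller set was found again: 88.3% of the regions of replicate 1 overlapped a region of replicate 2, and 64.3% of the regions of replicate 2 overlapped one of replicate 1. Regions placed by circular shifts along each chromosome overlapped in 1.19% of cases on average over 100 shifts, and in 1.32% at most. The regions of replicate 1 that were shared, 48179 in number, comprised 21346 at promoters and 26833 elsewhere.

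Sharing followed the height that the authors gave each region. In the tenth of regions with the greatest heights, 99.9% of replicate 1 and 99.8% of replicate 2 were shared. In the tenth with the lowest heights the shares were 54.6% and 14.5%. Across the 48179 overlapping pairs, heights on a log2 scale had a Pearson correlation of 0.939 and a Spearman correlation of 0.932 between the libraries. This correlation is across regions, which are not independent replicates. Of the 26510 regions present in replicate 2 alone, 54.7% overlapped the longer, more permissive list of replicate 1.

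Promoters made up a large share of the accessible DNA. Regions within 1000 bp of an annotated transcription start were 43.4% of all regions in replicate 1 and 39.2% in replicate 2 (mean 41.3% ± 2.92, SD, n = 2), whereas such windows covered 5.88% of the genome. A further 31.3% ± 2.02 lay in gene bodies and 27.4% ± 0.901 lay between genes (SD, n = 2). Promoter regions were higher than distal ones, with median heights of 1.40 and 0.949 in replicate 1 and 1.41 and 0.869 in replicate 2. Among the 1000 highest regions 92.2% and 86.3% were at promoters, against 14.1% and 7.20% among the 1000 lowest. Of 21911 protein-coding genes, 12991 had an accessible promoter in both libraries, 7805 in neither, 74 in replicate 1 alone and 1041 in replicate 2 alone.

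Among promoter regions of protein-coding genes, the highest by mean rank over both libraries was on chromosome 1 from 88277541 to 88277760. It lies over the starts of both Hjurp, the chaperone that loads centromeric histone, and Trpm8, the cold-sensing channel. Its height was 21 in replicate 1 and 23.6 in replicate 2. Starts of other genes were not ranked. The greatest height of any region, taken in each library on its own, was 36.2 in replicate 1 and 52.1 in replicate 2. The promoters of Abhd2 (15.5 and 15.3), Wwox (12.9 and 18.6) and Zfp143, a zinc finger transcription factor (12.6 and 13.7), followed, with those of the nuclear pore genes Nup153 (12.1 and 15.1) and Nup107 (11.6 and 15.3). The shared start of Acin1 and 1700123O20Rik had 14.3 and 15.0. The promoter of Dynlt1b had 15.0 and 15.1, but its sequence occurs 4 times in the assembly in near-identical form, so its height is uncertain.

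Pan-neuronal, glutamatergic, receptor and immediate early genes had accessible promoters almost without exception. All 12 pan-neuronal genes, among them Rbfox3 (NeuN), Map2, Snap25 and Syt1, were accessible in both libraries, as were all 18 genes of glutamate and GABA receptors, including Grin1 and Gria1. Of 14 genes of glutamatergic neurons, 13 were accessible in replicate 1 and 14 in replicate 2. The exception was Slc17a7, the vesicular glutamate transporter, which had a promoter region of height 1.20 in replicate 2 alone. All 16 immediate early genes, the transcriptional first responders to neuronal activity such as Fos, Egr1, Arc and Npas4, had accessible promoters, as did all 15 housekeeping genes. These 5 lists exceeded the other protein-coding genes, of which 59.6% and 64.0% were accessible, in both libraries. Their adjusted p-values ranged over the lists from 0.00103 to 0.0244 in replicate 1 and from 0.00372 to 0.0121 in replicate 2 (two-sided Fisher's exact test, Benjamini-Hochberg over 27 lists).

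Promoters of genes of other organs were mostly closed. Of 13 hepatocyte genes, 1 was accessible in replicate 1 and 3 in replicate 2, and albumin (Alb), Apoa1 and Apoa2 were in neither. Among 12 muscle genes 1 was accessible in each library, and Acta1 and Actc1 were not. The counts were 3 of 13 in each library for blood lineage genes, 2 of 12 for epithelium and skin, and 1 of 10 for pluripotency and germ line. Of 39 Hox genes, which pattern the body axis behind the forebrain, 2 and 7 were accessible, and of 1134 olfactory receptor genes 12 and 15. These 7 lists were below the other genes in both libraries, with an adjusted p of 0.0216 or smaller in each (two-sided Fisher's exact test). The lists were also set against random genes matched on CpG content within 500 bp of the outermost start of each gene. Genes were still called open at any of their starts, and the number of starts was not matched. The glutamatergic, immediate early, housekeeping, hepatocyte and blood lists lost their calls (permutation test, adjusted p up to 0.0585, 0.386, 0.104, 0.826 and 0.624). The olfactory receptor list stayed below the matched genes, but of those only 13.3% and 16.3% were accessible, so most of its difference was removed. A promoter distance of 2500 bp ended those of hepatocyte, muscle and blood genes, a distance of 500 bp that of glutamatergic genes, and the stronger 50% of regions that of the receptor genes. As the mean difference from other genes over the libraries, muscle went from -53.5 to -27.2 percentage points, hepatocyte from -46.5 to -33.9 and the receptors from 38.2 to 15.8, whereas blood (-38.8 to -33.9) and glutamatergic genes (34.6 to 29) moved less. Under CpG matching hepatocyte had -13.9, blood -14.7, immediate early genes 12.6, housekeeping 18.5 and glutamatergic genes 25.6.

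**Figure D1:**
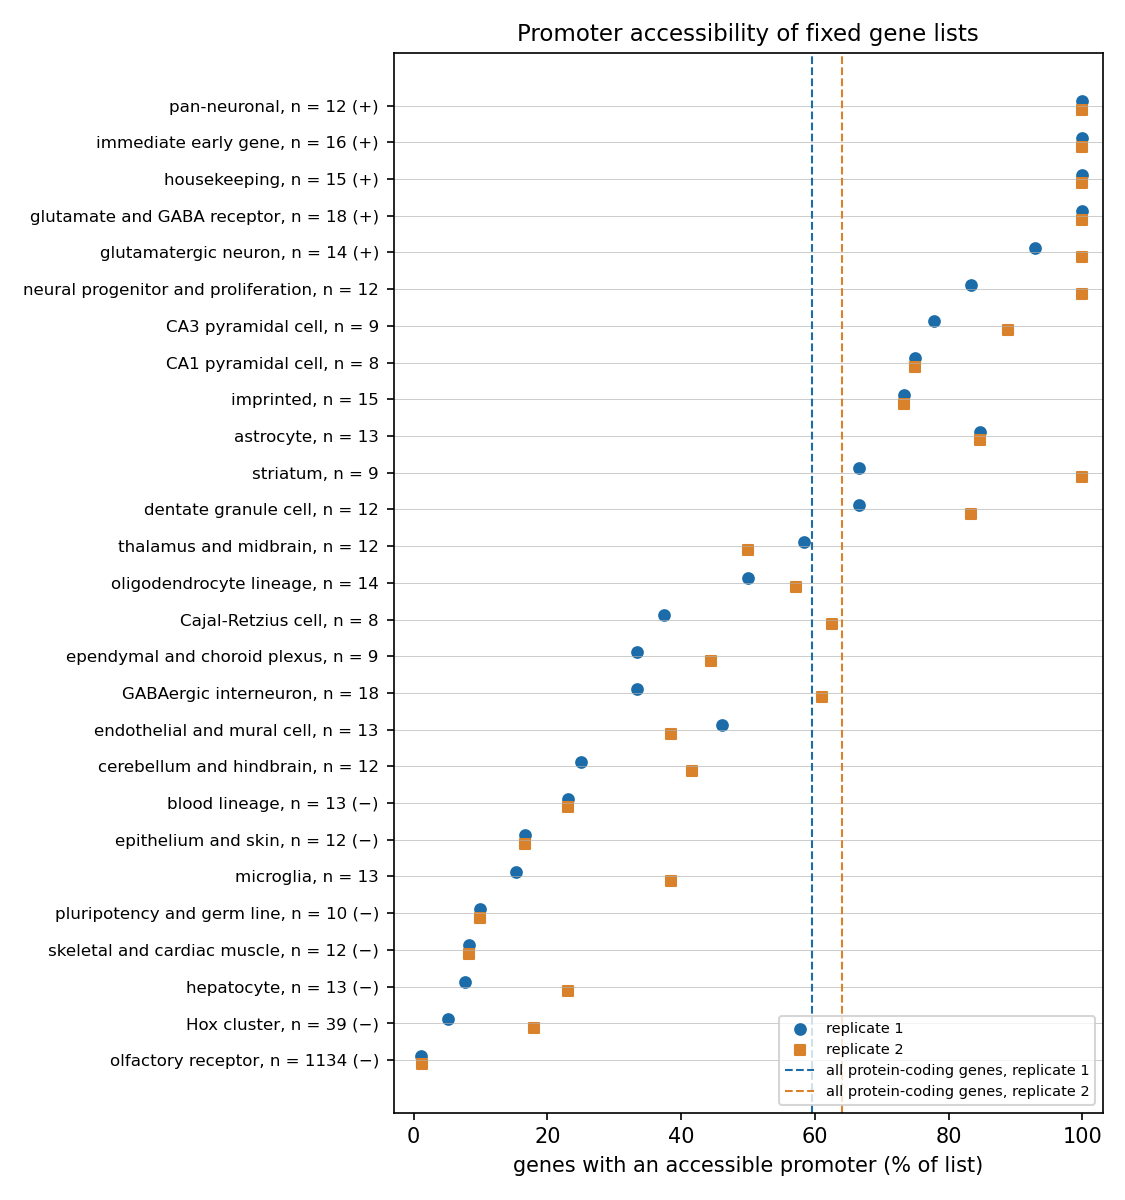
Share of the genes of each fixed list (y axis, n is the number of genes) with an accessible region within 1000 bp of a transcription start (x axis, %), for replicate 1 (circles) and replicate 2 (squares). Dashed lines give all protein-coding genes (59.6% and 64.0%), and plus and minus signs mark the 5 lists above and the 7 lists below other genes in both libraries.

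None of the lists of glial, vascular and interneuron genes passed the test in both libraries. Of 13 astrocyte genes, 11 were accessible in each library but only 9 in both. Aldh1l1 and Aqp4, the astrocyte water channel, were accessible in replicate 1 alone, and Fgfr3 and the glutamate transporter Slc1a3 in replicate 2 alone; in the longer lists all 4 had a promoter region in both libraries. Of 13 microglial genes, 2 and 5 were accessible, and Csf1r, C1qc and Tmem119 had a promoter region in replicate 2 alone, which in the longer lists held for Csf1r only. That list was below other genes in replicate 1 (adjusted p = 0.00712) and not in replicate 2 (adjusted p = 0.134, Fisher's exact test), but was below them in both libraries at a promoter distance of 500 bp. Of 18 genes of GABAergic interneurons, 6 and 11 were accessible. Gad1, which makes GABA, had heights of 2.43 and 2.61, whereas Gad2, Slc32a1, Dlx5, Vip and Sp8 were accessible in replicate 2 alone and Dlx1, Dlx2 and Dlx6 in neither. In the longer lists Gad2, Slc32a1, Dlx5 and Vip were open in both libraries, and Dlx1 and Dlx2 in replicate 1.

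Among the remaining lists, 7 and 8 of 14 oligodendrocyte lineage genes were accessible, with Mbp open in both libraries and Mag and Mobp closed. Endothelial and mural genes had 6 and 5 of 13, with Pdgfrb and Rgs5, markers of pericytes, in replicate 1 alone and Cldn5 in neither, though in the longer lists these 3 were open in both libraries. Neural progenitor genes had 10 and 12 of 12, and Eomes and Neurog2, factors of intermediate progenitors, were in replicate 2 alone (in the longer lists Eomes only). This list exceeded other genes only without replicate 1 (adjusted p = 0.0121, Fisher's exact test). The subfields of the hippocampus had 8 and 10 of 12 for dentate granule cells, 6 of 8 in each library for CA1 pyramidal cells, and 7 and 8 of 9 for CA3 pyramidal cells. Genes of Cajal-Retzius cells had 3 and 5 of 8, ependymal and choroid plexus genes 3 and 4 of 9, and imprinted genes 11 of 15 in each library. For other brain regions the counts were 7 and 6 of 12 for thalamus and midbrain, 3 and 5 of 12 for cerebellum and hindbrain, and 6 and 9 of 9 for striatum. The cerebellum and hindbrain list was below other genes in replicate 1 (adjusted p = 0.0354) and not in replicate 2 (adjusted p = 0.212, Fisher's exact test). Against genes matched on CpG content at the outermost start it was lower in both (permutation test, adjusted p = 0.0009 and 0.0027).

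The genes with most shared distal regions had long loci. Tcf4, a basic helix-loop-helix factor gene, held 26 shared distal regions in its body and the 10 kb on either side (33 in replicate 1 and 53 in replicate 2). Asic2 and Ntm each held 24, Camta1 held 23, Auts2 and Nav2 each held 21, and Phactr3 and Ptprn2 each held 20. Gm20388 and Fgfr2 held more, 117 and 46, but their annotated models span 4455 kb and 2981 kb with flanks and enclose 71 and 29 other protein-coding genes. The bodies of Camta1 and Asic2 enclose 4 and 1. Relative to length, the densest loci were those of the neighbours Ebi3 (53.3 per 100 kb) and Yju2 (44.5) on chromosome 17. The others of the 10 densest were Otx1 (42.7), Aurkb (30.7), Tchh (29.9), Sox4 (28.2), Ier5l (26.5), Zfp119b (25.7), Sncb (25.2) and Neurod2 (24.8). With their flanks the loci of Ebi3, Yju2 and Zfp119b overlap, so the same regions can be counted at more than 1 of them. Tchh had no promoter region in either library, and Neurod2 held 13 distal regions in replicate 1 and 6 in replicate 2.

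Within the fixed lists, distal regions also lay at genes with a closed promoter or one open in a single library. The astrocyte genes Aldh1l1 and Slc1a3 held 8 and 7 shared distal regions, the microglial gene Cx3cr1 held 8 and the endothelial gene Pecam1 held 7, the last pair with no promoter region in the shorter list of either library but with one in the longer list of replicate 1. The annotated body of Cx3cr1 encloses 4 other protein-coding genes, so its distal regions are not assigned to it alone. The CA1 gene Mpped1 held 4 and Fibcd1 held 3, also without a promoter region in the shorter lists; Fibcd1 had one in the longer list of replicate 2. Grik4 of CA3 held 10, Pdzd2 of dentate granule cells 12, Rbfox3 11 and Gria1 11. As groups, 0 of 27 lists differed from random lists matched on locus length, and 0 had an unadjusted permutation p under 0.05. In most lists the median was at most 1 shared region per gene, which leaves little room for a lower value. With the mean in place of the median, an alternative chosen after seeing the data, immediate early genes were higher (1.38 regions per gene against 0.487 in random lists, permutation adjusted p = 0.0459) and olfactory receptor genes lower (0.0653 against 0.478, permutation adjusted p = 0.0054). Without replicate 1 the median of 2 lists passed, glutamatergic and immediate early genes, and without replicate 2 that of 1 list, immediate early genes.

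The most crowded window of 100 kb in the genome, chromosome 7 from 79500001 to 79600000, held 30 shared regions, against a mean of 1.77 over 27268 windows. It contains Mir9-3 and its host transcript Mir9-3hg, the precursor of a microRNA of neural tissue, and part of a single protein-coding gene, Rhcg. The next, chromosome 13 from 23500001 to 23600000, held 28 shared regions and 15 histone genes of the Hist1 cluster. A window on chromosome 11 from 69000001 to 69100000 held 27, among Aurkb, Ctc1, Vamp2, a synaptic vesicle protein gene, and the clock gene Per1. Windows of Tcf4 (24 regions, chromosome 18 from 69300001), the gene of the nuclear factor Nfic (23, chromosome 10 from 81400001), Cic and Erf (26, chromosome 7 from 25200001), Phactr3 (21, chromosome 2 from 178100001) and the pair Thra and Nr1d1, a hormone receptor gene and a clock gene (21, chromosome 11 from 98700001), followed. The other windows of the first 10 were those of Abt1 and Btn1a1 (23, chromosome 13 from 23400001) and of Ptgis and B4galt5 (21, chromosome 2 from 167200001). Of these 10 windows, 7 overlapped the first 10 at 50 kb and 6 at 200 kb.

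The X chromosome, present once in each male cell, carried fewer and lower regions than autosomes. It had 8.52 regions per Mb in replicate 1 and 11.1 in replicate 2, against 21.5 and 29.4 on autosomes, a ratio of 0.387 ± 0.0127 (SD, n = 2). Median heights at X promoters were 0.805 and 0.819, against 1.42 and 1.44 on autosomes, and at distal regions 0.566 and 0.541 against 0.955 and 0.874. Promoters were accessible at 44.4% and 48.2% of X genes and at 60.8% and 65.3% of autosomal genes. The X chromosome also has fewer protein-coding genes per Mb, 5.54 against 8.44. With the stronger 50% of regions in each library the ratio of densities was 0.229. The Y chromosome had 39 and 33 regions, and chromosome 11 was the densest, at 32.6 and 44.5 per Mb.

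**Figure D2:**
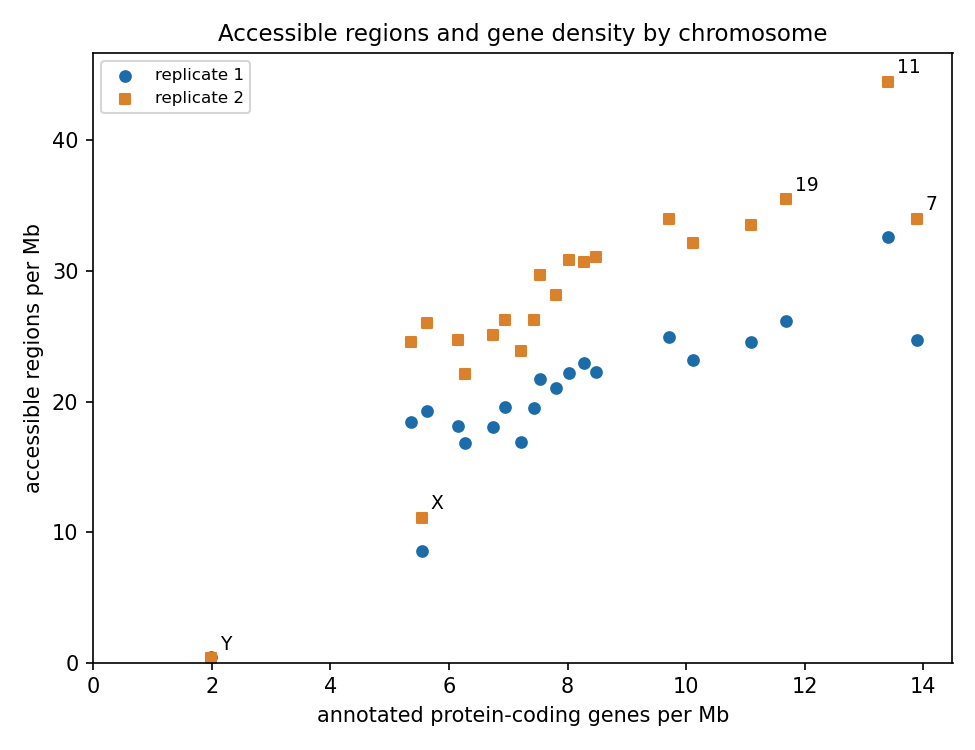
Accessible regions per Mb (y axis) against annotated protein-coding genes per Mb (x axis) for each chromosome, in replicate 1 (circles) and replicate 2 (squares). The X chromosome, at 5.54 genes per Mb, has 8.52 and 11.1 regions per Mb, below every autosome in the same library.

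Of the 30 binding motifs counted in the shared distal regions, CTCF, RFX and the full site of nuclear factor I had the highest ratios to control windows among those with at least 1 match in the controls. The motif of CTCF, the insulator protein, occurred in 14.8% of 25813 distal regions and in 0.112% of control windows matched on length and GC content, a ratio of 132 (95% exact interval 91.8 to 197). The full palindromic site of the nuclear factor I family was 13.7 times as frequent (4.36 to 69.0) and the RFX site 29 times (7.67 to 245), with 3 and 2 matches in the controls. The motif of the NEUROD type of basic helix-loop-helix factors, the drivers of excitatory neuron fate, occurred in 9.16% of regions and 4.45% of controls, a ratio of 2.06, as high as that of the ASCL type (2.06). The motif of MEF2, a factor family regulated by neuronal activity, had a ratio of 2.47, that of CRE, the cyclic AMP response element, 2.32, and that of EGR 3.44. The REST site was found in 13 regions and in no control, a ratio of 4.33 with the control count set to the floor of 3. In all, 17 of 30 motifs were more frequent than in controls and 1, the site of the blood factors GATA, was less frequent (ratio 0.569, adjusted p = 0.000245, two-sided Fisher's exact test, Benjamini-Hochberg over 30 motifs).

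The motifs that did not pass the test included some of factors of other tissues and some of brain factors. HNF4 (ratio 0.770), HNF1 (0 regions and 1 control), FOXA (1.26) and PU.1 (5 regions and 4 controls) were among the former. The site of TBR and EOMES (0.636) and that of the ZBTB18 type (1.10), factors of glutamatergic neurons and their progenitors, were among the latter, and SRF (1.08) did not pass either. Against flanks not matched on GC content ETS, NF-Y, SRF, YY1 and the ZBTB18 type gained a call in the higher direction (SRF ratio 3.20, adjusted p = 0.0399, Fisher's exact test), and FOXA one in the lower direction. In replicate 1 on its own 16 motifs were enriched and in replicate 2 on its own 18. Ratios over few control matches differed between the libraries, with 244 and 113 for CTCF, 14 and 39.5 for RFX and 14.3 and 8.29 for the full site of nuclear factor I, so their size is uncertain beyond the printed intervals. CTCF had 266 in the stronger 50% of regions, where the full site of nuclear factor I had 6.5 and ASCL 1.38. Against flanks not matched on GC content CTCF had 202, EGR 20.5, ASCL 3.90 and GATA 0.340. Calls for AP-1, MEF2 and POU were lost both in the stronger 50% of regions and against flanks not matched on GC content, and those of NRF1, SOX and REST in the former only. The ratio of NRF1 was not smaller there (4.5, against 3.80), over 9 regions and 2 controls. The TEAD call was lost against flanks not matched on GC content (ratio 1.12) and without replicate 2 (1.20). MEF2 had 1.83 in the stronger 50% of regions and 1.21 against those flanks. In the stronger 50%, POU had 1.35 and SOX 1.13. The LHX and DLX homeobox site turned to a call in the lower direction against those flanks (ratio 0.730, adjusted p = 7.3e-05, Fisher's exact test). POU turned to 0.920 against the flanks, and AP-1 to 0.951 in the stronger 50% of regions, both without a call.

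**Figure D3:**
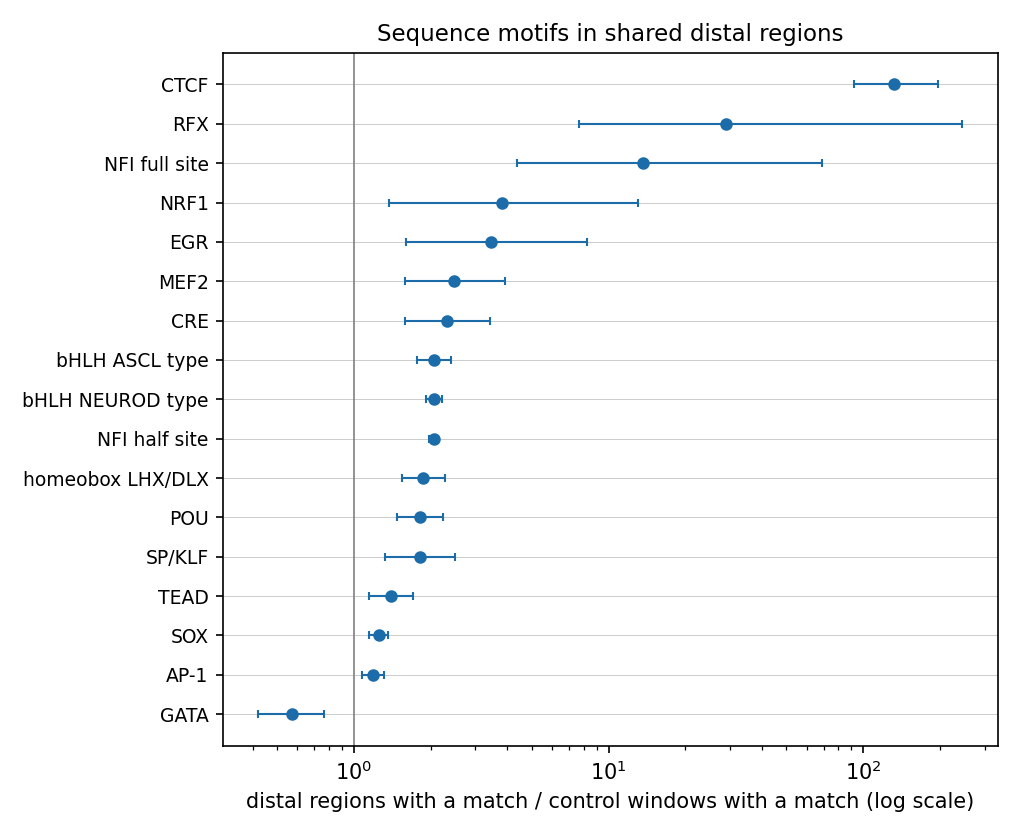
Ratio of shared distal regions with a motif match to control windows with one (x axis, log scale) for motifs past the test with at least 1 match in the controls (y axis). Points are ratios over 25813 region and control pairs and bars are 95% exact intervals; CTCF stands highest at 132 and GATA is the only motif below 1, at 0.569.

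Footprints were called at 226223 sites in replicate 1 and 345745 in replicate 2. They fell inside the regions of the shorter list in 67.2% and 64.5% of cases and inside the longer list in 90.7% and 87.7%. About as many lay in promoter regions (33.9% and 30.4%) as in distal regions (33.3% and 34.1%). Footprints recurred less than regions did: 58.2% of those of replicate 1 overlapped a footprint of replicate 2, and 37.1% in the other direction. Within shared regions 69.6% of replicate 1 footprints recurred, against 46.9% ± 0.0828 (SD over 20 draws) for footprints placed at random in the same regions.

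The motif that was most often footprinted was that of CTCF. A footprint overlapped 98.4% of its matches in distal regions in replicate 1 and 98.8% in replicate 2, against 36.9% and 41.4% for shuffled forms of the motif, a ratio of 2.53 ± 0.200 (SD, n = 2). The full site of nuclear factor I had a ratio of 2.71 ± 0.159, with 88.4% and 93.1% of matches footprinted, and CRE 1.88 ± 0.0213. RFX sites were footprinted in 91.5% and 92.5% of cases and REST sites in 92.9% and 97.2%, with no shuffled match to compare. NEUROD type sites reached 46.9% and 41.7%, a ratio of 1.42 ± 0.0640, below that of HNF4 sites, which were not enriched in number (1.56 ± 0.157). Sites of the ASCL type (0.658 ± 0.0263), AP-1 (0.891 ± 0.0226), the LHX and DLX homeobox site (0.871 ± 0.0169), GATA (0.811 ± 0.191), FOXA (0.825 ± 0.193), POU (0.958 ± 0.0532) and ROR (0.947 ± 0.00870) were footprinted less often than their shuffled forms in both libraries (SD, n = 2 throughout). Of 22 motifs with at least 20 matches and 20 shuffled matches in each library, 13 had ratios above 1 in both libraries. When the whole match had to lie inside the footprint, the ratio was 14.9 for CTCF and 16.2 for the full site of nuclear factor I, and those of GATA (1.89) and POU (1.20) turned above 1.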

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

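The strict list against the longer list of the other library, the longer list for the X chromosome, footprints inside shared regions and the mean per gene were chosen after seeing the data; the other alternatives were planned. No paired analysis was possible because there is 1 group. A stricter limit on footprints could not be run, since every footprint carries the same value. The number of regions was 32206 per library in the stronger 50% and 112700 in the longer list, by construction, and 54546 to 74278 with 1 replicate. Sharing, as the mean of both directions, was 76.3% in the main setting and 63.5% to 88.7% under the 5 alternatives. The directions differ with the lengths of the lists, so the spread between them is no measure of replicate variation. With equal numbers of regions they gave 79.9% and 79.0%. The promoter share was 35.5% at 500 bp, 49.2% at 2500 bp and 51.4% in the stronger 50%. The X to autosome ratio was 0.229 in the stronger 50%, where a single height limit per library leaves out more of the lower regions on X. Why heights on X were lower stays open. Footprint sharing inside shared regions was 63.4%, since regions of a single library were removed. The correlation of heights was 0.943 with reciprocal overlap of 50%, and 6 of 10 windows recurred at 200 kb.

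Of the promoter lists, 2 were higher against CpG-matched genes, and 4 were lower at 2500 bp and 11 in the stronger 50%, where GABAergic, cerebellar, endothelial and microglial genes were added; the cause was not tested. With 1 replicate 5 to 6 lists were higher and 7 to 9 lower. Distal lists went from 0 to 1 higher and 1 lower with 50 kb flanks, to 1 higher and 1 lower with the mean per gene, and to between 1 and 2 higher with 1 replicate; the cause was not tested. Of the motifs, 11 were higher in the stronger 50%, which holds fewer regions, and 3 were lower against flanks without GC matching. With pseudocounts of 0.5, AP-1 turned to a ratio of 0.952 in the stronger 50%, and against flanks without GC matching POU turned to 0.921, the homeobox site to 0.730 and FOXA to 0.661; the flanks differ in GC by construction. With the whole match inside a footprint, 14 motifs had ratios above 1 in both libraries; 20 of 22 single ratios moved, with CTCF at 14.9, the full site of nuclear factor I at 16.2, TEAD at 0.990, NF-Y at 0.951, POU at 1.20 and GATA at 1.89; the cause was not tested. No result was limited by a known depth, since depth was not given in the sources used here.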

Other observations

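The tests of X chromosome gene density and of cell mixture, the 80% limit for nuclear copies and the merging of overlapping regions were chosen after the results were seen. The other tests were written before their own values were known, but after the lower heights on X as a whole and the overlap of unshared regions with the longer lists had been seen.

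The 20 highest shared distal regions included several in unusual sequence, as well as ordinary distal sites. The first lay in an exon 10.2 kb from the nearest protein-coding start, that of Cox14, on chromosome 15 from 99735661 to 99735920, with heights of 28.4 and 26.3. The others in the first 5 lay near Igf2bp3 (21.1 and 31.2), Lars2 (17.5 and 31.5), Il31ra (19.1 and 27.7) and Gm8797 (18.5 and 26.1). Those farther down, near Ptma, Pllp, Txn2, Mxi1 and Foxk1, had heights of 7.96 to 10.9. The genes are named as the nearest protein-coding start, after the values were seen.

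Reads that belong to other copies of a sequence may raise some of the highest distal regions. Mitochondrial sequence inserted in the nuclear genome was searched for at 80% identity over 80% of the region length. It was found in 0 of 19, with a pair of overlapping regions near Gm21887 counted once, and in 0 of 1000 other shared distal regions. Insertions of that kind were thus not seen, but shorter or more diverged ones could be missed. Sequence with near-identical nuclear copies remained open for part of them: 3 of 19 had another copy at 90% identity and length, near Il31ra, Gm8797 and Gm21887, against 17 of 1000 other shared distal regions (Fisher's exact test, p = 0.00513). At 80% identity and length 7 of 19 had one, against 31 of 1000. For the other 12, which include the highest, a copy absent from the assembled chromosomes was not tested, and no biological explanation was tested.

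Whether the single copy in male cells accounts for the lower heights on the X chromosome stays open. At distal regions with a CTCF match, the median height on X was 0.502 of that on autosomes in replicate 1 (95% bootstrap interval 0.409 to 0.565) and 0.432 in replicate 2 (0.364 to 0.482), a mean of 0.467. The interval of replicate 2 lies below 0.5, whereas the medians over all distal regions, 0.566 against 0.955 and 0.541 against 0.874, give ratios above it. Only called regions enter these medians, and those below the calling limit are left out. A single copy therefore need not give a ratio of 0.5, and these ratios cannot decide it. The lower gene density of the X chromosome is not enough for its lower number of regions, since regions per protein-coding gene on X were 0.589 of those on autosomes (0.602 and 0.575). Mapping of reads to the reference, and sequence repeats on X, were not tested and stay open, and no female sample was analysed.

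The cause of the larger number of regions in replicate 2 stays open. Regions nearer to the calling limit in replicate 1 are one candidate: of the 26510 unshared regions of replicate 2, 54.7% were in the longer list of replicate 1 and the rest were not. A planned test, the 97.9% of the stronger 50% of replicate 2 regions found in that list, decides nothing, since the unshared regions are mostly weak ones. A different mix of cell types in the dissections stays open too. Of 13 cell class lists, 2 had a median height ratio outside the central 95% of random sets of shared regions matched on height. They were astrocyte genes (log2 ratio 0.19 against 0.32 for all shared regions, percentile 0.1) and neural progenitor genes (0.16, percentile 0.36). Both were relatively lower in replicate 2. Among lists that are not cell classes, Hox genes also lay outside, relatively higher in replicate 2 (0.65, percentile 98.8). The random sets drew single regions, whereas several regions of a list share a gene, so these percentiles may overstate the difference. With 1 library on each side the ratios describe these libraries and cannot be told apart from a technical difference.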
